A study of Mus musculus with 12 samples.

How the data were processed

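The series holds 12 samples of RNA from the chromatin-associated fraction of E14TG2a mouse embryonic stem cells, an immunoprecipitated and an input sample for each of 2 replicates of 3 genotypes. Per the labels' protocols, ribosomal RNA was depleted, m6A spike-in RNA was added before the RNA was fragmented, part of the fragments was saved as input and the rest went through an m6A antibody. The submitters' processing notes name fastp, HISAT2, SAMtools, Picard, MACS2, featureCounts and bedtools and the GRCm39 assembly. They give no version, and no role or order for each tool. Whether replicates were pooled to define intervals is not stated, and neither is the step at which the ERCC RNAs were added.

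Both deposited tables hold a spike-in-scaled read signal for 6 libraries, 1 for genomic intervals and 1 for annotated repeat loci. Each value is a whole number of reads times 1 factor per library, and 100% of the values in both tables gave whole reads within a tolerance of 1e-06. The deposited signal of the m6A-modified spike-in is the same in all 6 libraries, so the factor is set by the reads of that RNA. The design written before the data were examined had assumed CPM, and the tests kept its form on the signal instead. Columns were read as immunoprecipitated because the submitters call the tables normalized m6A matrices. WT and KO are given in the column names, and the columns named KI were read as ΔcIDR by elimination. Both KO columns are named KO6. What the 6 stands for is not stated, so both KO libraries may come from 1 line. The column names themselves do not say immunoprecipitated or input. With 0 columns read as input, each comparison is between libraries read as immunoprecipitated, and RNA levels, repeat levels in input and enrichment over input were not analysed here.

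Depth ranged from 13234793 to 15145206 interval reads per library. At the spike-in, 814 to 1870 reads set the deposited scale, and the confidence intervals at the 95% level of ratios between spike-ins cover counting error only, as do limits for a count of 0, taken as 3 reads. Intervals carry coordinates as deposited. Whether a start is counted from 0 or from 1 is not stated. The tables hold no gene names and the reference at hand is not on GRCm39, so the gene lists, the cell type markers and the check of Alkbh5 itself were not used here.

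Intervals were assigned to a repeat family where at least 50% of their length was covered by its loci, with bedtools 2.31.1. Family names in the tables carry no subfamily, so the lists fixed before the data were examined were used at the level of families. Young and older LINE-1 were merged, IAP, ETn and other ERVK were merged, and the ERVL family stood in for the MERVL list, a choice made after the names had been seen. The other lists were ERV1, MaLR, SINE B1, SINE B2, SINE B4/ID, satellite, DNA transposons, simple and low-complexity repeats, and structural RNA. For families, signal was summed over loci, and 58 families were tested, leaving out the simple and low-complexity classes and families below the minimum.

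Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, figures were drawn with matplotlib 3.10.9, and tests were run in R 4.3.3. The log2 of signal plus 0.5 was fitted with limma 3.58.1, with 1 mean per group over all 6 libraries and a trend in the prior variance, for features with a mean signal of at least 1. Folds on this scale understate the change of intervals near 0. Adjusted p-values follow Benjamini and Hochberg, with calls at 0.05. The lists were tested with camera from limma, with a preset correlation of 0.01 and again with an estimated one. edgeR 4.0.16 was run on whole reads with its quasi-likelihood test, with library sizes that keep the deposited scale and with TMM factors. A list's relative change is the median over its intervals of the difference between group means of log2 signal, minus the same median over all tested intervals. Its standard error comes from medians per library, which are taken over the list after centring each library and subtracting each interval's WT mean. Those medians are the ones plotted by library and can differ from the relative change.

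Intervals to be named were, by a rule written before the data were examined, the 10 with the largest log2 change in each direction of each comparison among those past an adjusted p of 0.05 whose libraries did not overlap. Families were the 8 largest in each direction, or the 3 with the smallest p where fewer than 3 passed. The text gives a selection of these intervals. Where a group had 3 reads or fewer in total, no fold is given.

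Chromosome profiles used repeat loci outside the intervals with a mean of at least 20 reads, in log2 of RPM plus 0.05, each library centred on its median, in bins of 10 Mb with at least 50 loci. A first run with a minimum of 10 reads and 0.5 RPM had been seen before these settings were chosen. The bounds of 8 and 56 Mb on chromosome 11 were picked from the profile itself, so the size of that shift is not independent of its choice. The limma and edgeR steps were tested on simulated data for KO against WT, with 200 of 37759 intervals changed. Each interval was drawn with the same dispersion, 0.0223, and the library factors were taken as exact. At 2-fold limma recovered 42% with 3 false calls and edgeR 46% with 5.

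Alternatives named before the data were examined were pseudocounts of 0.1 and 2, no filter and a minimum of 5, centring of each library on its median, a replicate block, limma without trend, edgeR, the unmodified spike-in scale, an estimated correlation and leaving out each library in turn. Those chosen after seeing the data were the ERCC scale, the scale of reads in repeats outside intervals, centring on total repeat signal, any overlap with a repeat, edgeR on the deposited scale, a block after centring, and leaving out chromosomes 6 and 8 and 8 to 56 Mb of chromosome 11. A set's change of sign was at first to count as reversed where its libraries did not overlap, and this was changed to sets called by camera after the values had been seen.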

Results

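The series measured N6-methyladenosine (m6A) in RNA attached to chromatin in mouse embryonic stem cells of the E14TG2a line. RNA from the chromatin-associated fraction was immunoprecipitated with an m6A antibody and sequenced. The cells were wild type (WT), lacked Alkbh5, an enzyme that removes m6A (KO), or carried an Alkbh5 deletion named for an intrinsically disordered region of the protein (ΔcIDR). The values described here come from 6 libraries, 2 per group, which were read as immunoprecipitated from the title of the tables, as the column names do not say immunoprecipitated or input. The columns read as ΔcIDR are named KI in the tables and were assigned by elimination. The tables used held 0 columns read as input, so a difference between groups can come from m6A, from the amount of RNA or from the number of gene copies. Nothing in the labels states that replicates came from separate cultures, so each p-value measures only the spread between these samples. The limma errors and p-values also borrow that spread from all features of like signal. A small limma p therefore does not show that an interval's own 2 libraries agree.

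The tables cover 74299 intervals and 4929385 repeat loci on the GRCm39 assembly. Interval reads came to 13234793 and 13386543 in the WT libraries, 14657271 and 13611019 in the KO libraries and 14491339 and 15145206 in the ΔcIDR libraries. Reads in repeats came to 21908485 and 21864369 in WT, 26267351 and 23336824 in KO and 20922839 and 21666970 in ΔcIDR. The deposited signal is scaled by reads of an m6A-modified spike-in RNA, which numbered 1172 and 1106 in WT, 1379 and 1870 in KO and 814 and 849 in ΔcIDR. One read was therefore worth between 0.0729 and 0.168 units of signal in the interval table and between 1.45 and 3.33 in the repeat table. An unmodified spike-in had more reads than the m6A spike-in in all 6 libraries, which is unexpected after an m6A immunoprecipitation unless much more of it was added. The amounts added are not stated and the spike-ins are known here only by the names of their table entries, so 2 points stay open for each value below, whether the libraries are immunoprecipitated ones and how well the deposited scale follows m6A recovery. Low-level intervals were common, since 51.1% had a mean below 10 reads.

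The intervals had a median length of 373 bp, from 200 to 13148 bp, and together covered 39.6 Mb. LINE-1 (L1) elements covered at least 50% of 38050 intervals, or 51.2% of them, and 24630 intervals, or 33.1%, had no family covering that much. The latter are called intervals without a repeat below, although they may overlap repeats over less of their length. Among the 37759 intervals with enough signal to be tested, L1 accounted for 21.9% and intervals without such a repeat for 59.2%. Ribosomal RNA repeats took 0.00202% of repeat reads or less in each library.

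Total signal over the intervals was highest in ΔcIDR on the deposited scale, at 2428466 and 2433411 in its libraries. The WT libraries had 1540414 and 1651054 and the KO libraries 1449896 and 992881. The ΔcIDR total was 1.52-fold the WT total and 2.03-fold the KO total, at 0.61 ± 0.05 and 1.02 ± 0.27 (SE) on the log2 scale. KO differed from WT by −0.41 ± 0.28 (SE) on the log2 scale, less than 2 standard errors. With 2 libraries per group the smallest two-sided exact permutation p is 0.333, so no p is given for these totals. Scaled by ERCC reads in the same libraries, ΔcIDR differed from WT by −0.049 ± 0.07 (SE) and KO by −0.0082 ± 0.08 (SE). Scaled by reads in repeats outside the intervals, ΔcIDR was 0.23 ± 0.02 (SE) above WT, 1.17-fold, and KO was −0.12 ± 0.05 (SE) from WT. Scaled by the unmodified spike-in, ΔcIDR lay on the other side of WT, at −0.57 ± 0.73 (SE).

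**Figure D1:**
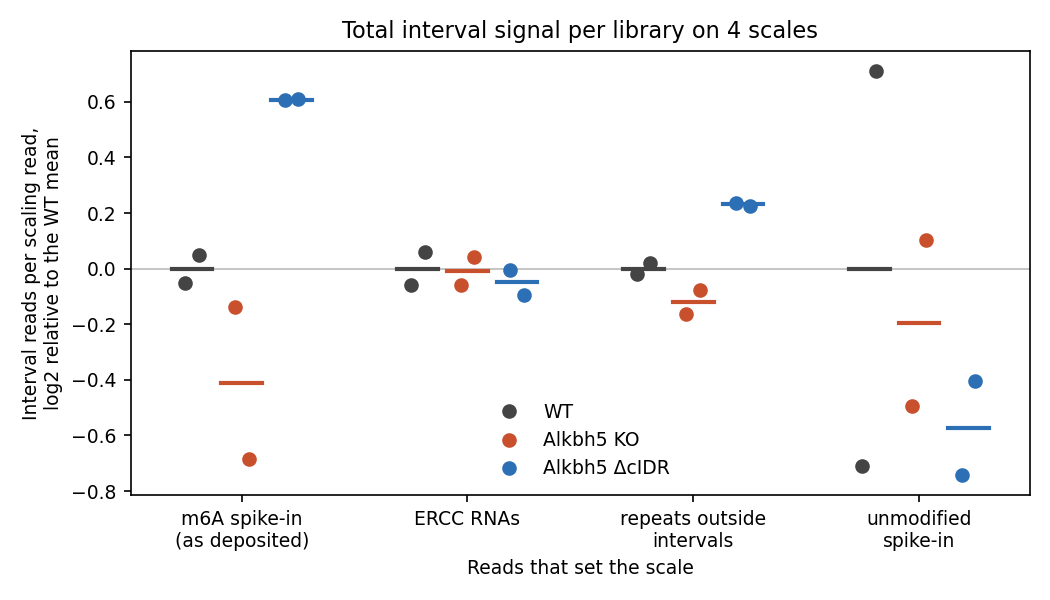
Total reads in intervals per scaling read, as log2 relative to the WT mean, for 4 scaling choices; points are libraries and bars are group means. The ΔcIDR libraries sit 0.61 above WT on the deposited m6A spike-in scale, −0.049 from it on the ERCC scale, 0.23 above it on the scale of reads in repeats outside intervals and −0.57 from it on the unmodified spike-in scale.

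KO against WT asks what loss of Alkbh5 does to m6A on chromatin-associated RNA. Intervals made of ERVL, the endogenous retrovirus family that includes MERVL, stood apart. Their median stood 0.90 ± 0.15 (SE) above that of all intervals on the log2 scale, 1.87-fold, and 1667 of the 1786 ERVL intervals (93.3%) lay above the median change. Satellite intervals lay −0.30 ± 0.08 (SE) from all intervals (−0.19 without WT replicate 2), ERVK intervals −0.20 ± 0.03 and ERV1 intervals −0.10 ± 0.04 (−0.066 without KO replicate 1). Other lists lay as far, simple and low-complexity intervals at −0.24 ± 0.10 (SE; −0.12 without WT replicate 2) and SINE B2 intervals at −0.20 ± 0.05 (SE). L1 intervals lay at 0.13 ± 0.13 (SE), from 0.010 without KO replicate 2 to 0.26 without KO replicate 1, and their KO and WT libraries overlapped.

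The median tested interval lay −0.35 from WT on the deposited scale, a shift that includes the spike-in factors. With limma, 372 intervals were higher and 3784 lower in KO at an adjusted p of 0.05. After each library was centred on its own median the counts were 1767 higher and 2747 lower, and the share of higher calls went from 8.95% to 39.1%. It was 45.2% with TMM factors, 51.6% on the ERCC scale and 33.5% on the scale of reads in repeats outside intervals. edgeR on the deposited scale called 4189 intervals, and limma on the unmodified spike-in scale called 18. The 4156 limma calls became 10775 without KO replicate 1, 1356 without KO replicate 2, 1510 without WT replicate 1 and 667 without WT replicate 2. In simulated data the same test recovered 0% of 1.5-fold changes, 42% of 2-fold changes and 91.5% of 4-fold changes. The simulation held 200 changed intervals, 1 dispersion for all intervals and exact library factors. It lacked the error of the spike-in scale, so these rates do not carry over to the calls above.

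Among single intervals, those with the largest rise in KO had low signal in WT. An L1 interval on chromosome 3 (91049922 to 91050320) had a signal of 31.5 ± 5.79 in KO and 0.836 ± 0.135 in WT (SD, n = 2 each), a log2 change of 4.58 ± 0.42 (SE). A pair of intervals on chromosome 2 (27656206 to 27656458 and 27649259 to 27649462) rose together, the second from 0.599 ± 0.0246 to 14.7 ± 5.59. On chromosome 7, an interval without a repeat (40806620 to 40807237) rose from 1.85 ± 0.517 to 24.7 ± 7.65. Among losses, an ERV1 interval on chromosome 17 (6844428 to 6846145) fell from 255.2 ± 30.2 to 13.1 ± 3.16, a log2 change of −4.25 ± 0.31 (SE) with a limma adjusted p of 2.0e-37, and 2 further intervals nearby (6787078 to 6787369 and 6782735 to 6783681) fell by 3.10 and 3.09 on the log2 scale. An ERVK interval on chromosome 9 (13668927 to 13669139) fell from 106.9 ± 8.66 to 6.40 ± 0.181, and an interval on chromosome 13 without a repeat (25386008 to 25386409) from 22.4 ± 0.438 to 0.526 ± 0.184.

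The set test camera compares a list with all other intervals and assumed a correlation of 0.01 within lists. On the deposited scale it placed ERVL above other intervals (adjusted p = 1.9e-47, and adjusted p = 0.889 with an estimated correlation). Satellite (adjusted p = 0.00120), ERVK (adjusted p = 0.00163), L1 (adjusted p = 0.00285), simple and low-complexity (adjusted p = 0.00285) and ERV1 (adjusted p = 0.0362) were the other lists called by camera. Each of these 5 had adjusted p = 0.939 with an estimated correlation, so 0 lists passed in that form. L1 was called as higher although its median change was −0.22 on the deposited scale, because the other intervals lay lower. Counts for the lists were 94 higher and 20 lower of ERVL, 44 and 357 of L1, 15 and 264 of ERVK, 1 and 49 of ERV1, 2 and 91 of satellite, and 3 and 161 of simple and low-complexity intervals. Adjusted over the list alone, 55 ERVL, 269 L1, 351 ERVK, 58 ERV1, 128 satellite and 211 simple and low-complexity intervals passed. After centring, 561 ERVL intervals were higher and 13 lower, and 921 passed adjusted over the list alone. The centred counts were 154 and 173 of L1, 38 and 177 of ERVK, 10 and 40 of ERV1, 7 and 54 of satellite, and 13 and 85 of simple and low-complexity intervals, so most of the tilt of L1 calls to the lower side came with the scale.

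On the deposited scale the lists that camera did not call in KO against WT were MaLR, SINE B1, SINE B2, SINE B4/ID, DNA transposons and structural RNA. After centring it called SINE B2 below other intervals (adjusted p = 0.0496, and adjusted p = 0.310 with an estimated correlation) and no longer ERV1 (adjusted p = 0.0807). On the deposited scale MaLR had 12 higher and 108 lower, B1 3 and 47, B2 2 and 30, and B4/ID 1 and 16, with 120, 56, 32 and 20 passing when adjusted over the list alone. After centring the counts were 44 and 63 for MaLR, 11 and 36 for B1, 6 and 20 for B2, and 3 and 10 for B4/ID. Of 28 DNA transposon intervals 2 were lower. With limma 0 of the 13 structural RNA intervals passed, over all intervals or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Summed over all loci of each family, 0 of 58 repeat families passed limma on the deposited scale, against 2 at an unadjusted p under 0.05, and 54 passed without KO replicate 1 and 6 without KO replicate 2. The families with the smallest p were Satellite/Y-chromosome, ARTEFACT and srpRNA, at −0.67 ± 0.32, −0.77 ± 0.37 and −0.57 ± 0.30 (SE), each with a limma adjusted p of 0.687, and 1 locus held 63.1%, 93.9% and 45% of their reads. After centring 7 families were higher and 4 lower, among them ERVL at 0.21 ± 0.07 (limma adjusted p = 0.0280) and Satellite/Y-chromosome at −0.38 ± 0.05 (limma adjusted p = 7.6e-10). The ERVL family call was lost on leaving out any library other than WT replicate 2, and the Satellite/Y-chromosome call on leaving out WT replicate 2.

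**Figure D2:**
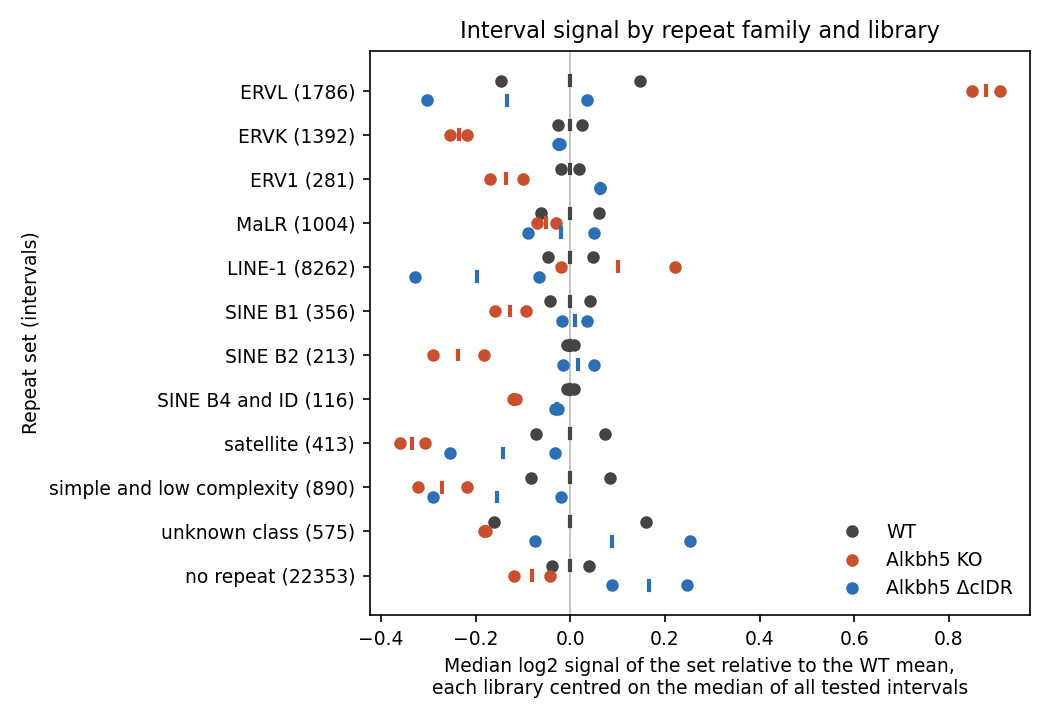
Median log2 signal of each repeat list per library, centred on all intervals of that library and relative to the WT mean; points are libraries and ticks are group means. The ERVL list stands at 0.85 and 0.91 in the KO libraries and at −0.30 and 0.036 in the ΔcIDR libraries, and ERVK at −0.22 and −0.25 in the KO libraries.

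ΔcIDR against WT asks whether the disordered region is needed for the enzyme's effect on m6A. Most intervals shifted together on the deposited scale, with a median of 0.46. The repeat lists differed from that shift by at most 0.28, while some single intervals, given below, differed far more. Simple and low-complexity intervals lay −0.24 ± 0.16 (SE) from all intervals, satellite −0.22 ± 0.13 (SE) and structural RNA 0.25 ± 0.27 (SE). In each of these lists the ΔcIDR and WT libraries overlapped. L1 intervals lay −0.28 ± 0.14 (SE) from all intervals, at −0.44 without ΔcIDR replicate 1 and −0.10 without ΔcIDR replicate 2. ERVL intervals lay at −0.21 ± 0.22 (SE), within 1 standard error of all intervals, and went from −0.35 without WT replicate 2 to −0.078 without ΔcIDR replicate 1. Losses included a pair of intervals on chromosome Y, where the interval from 90839411 to 90839803 fell from 10.1 ± 1.01 to 0.995 ± 0.726 (SD, n = 2 each; log2 change −2.92 ± 0.39 SE, limma adjusted p = 5.4e-10) and that from 90837458 to 90838052 fell from 17.6 ± 4.79 to 2.55 ± 0.656. By median, chromosome Y was also lower. Its 142 tested intervals had medians of −0.24 and −0.54 in the ΔcIDR libraries, relative to the WT mean after centring. Whether the pair is part of that shift was not tested. The losses named by rule also held an interval on chromosome X (168754676 to 168754908), from 10.5 ± 1.36 to 2.32 ± 1.23.

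Among intervals that rose, one on chromosome 11 (94410697 to 94410907) went from 0.243 ± 0.179 to 21 ± 6.77 and an ERVK interval on chromosome 15 (34228906 to 34229159) from 0.483 ± 0.189 to 13.9 ± 0.183. An interval on chromosome 5 (31287727 to 31287935) rose from 6.88 ± 3.44 to 51.5 ± 9.19, a log2 change of 2.89 ± 0.36 (SE). Chromosome Y also held a gain, from 1.75 ± 0.665 to 20.5 ± 0.550 (725352 to 726627). A B2 interval on chromosome 14 (14490174 to 14490426) had 35.3 ± 45.1 in ΔcIDR, so that value rests on 1 library and the call was lost without ΔcIDR replicate 1.

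With limma, 393 intervals were higher and 33 lower in ΔcIDR on the deposited scale, and edgeR called 303. After centring the counts were 63 higher and 52 lower, and the share of higher calls went from 92.3% to 54.8%. That share was 53.4% with TMM factors, 25.9% on the ERCC scale and 84.5% on the scale of reads in repeats outside intervals. The 426 limma calls became 30 without WT replicate 1, 74 without WT replicate 2, 73 without ΔcIDR replicate 1 and 47 without ΔcIDR replicate 2. Without KO replicate 1 or 2, which take no part in this contrast but add to the pooled spread, there were 10177 and 10234. camera placed L1 (adjusted p = 3.8e-17), simple and low-complexity (adjusted p = 5.1e-07), ERVL (adjusted p = 1.7e-06), satellite (adjusted p = 1.6e-05) and MaLR (adjusted p = 0.0301) below other intervals, and structural RNA above them (adjusted p = 2.5e-04). None of these 6 lists kept its call, as each had adjusted p = 0.893 with an estimated correlation. Medians of the lower lists were above 0 on the deposited scale, because camera compares a list with other intervals.

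Calls in the ΔcIDR lists were few. On the deposited scale they were 10 higher and 7 lower of L1, 60 and 3 of ERVK, 22 and 1 of ERV1, 3 and 1 of ERVL and 1 and 1 of satellite, and after centring 0 and 12, 13 and 5, 12 and 1, 0 and 1, and 0 and 2. Adjusted over the list alone, 0 L1, 89 ERVK, 51 ERV1, 1 ERVL, 2 satellite, 2 MaLR, 3 simple and low-complexity and 9 structural RNA intervals passed with limma, where 485 L1 intervals had an unadjusted p under 0.05. On the deposited scale 0 of 58 families passed limma, against 5 at an unadjusted p under 0.05, and 47 passed without KO replicate 1 and 47 without KO replicate 2. L1-Tx1, srpRNA and snRNA had the smallest p, at 0.80 ± 0.35, 0.63 ± 0.30 and 0.62 ± 0.30 (SE), each with a limma adjusted p of 0.457. A single locus held 73.3%, 45% and 15.3% of their reads, and L1-Tx1 had only 28 loci. After centring 4 families were higher and 8 lower. With chromosomes 6 and 8 and 8 to 56 Mb of chromosome 11 also left out, 5 were higher and 1 lower. The scale of reads in repeats outside intervals gave 2 higher and 0 lower, and the ERCC scale 0 higher and 45 lower. Centring on total repeat signal gave 0, so the balance depended on the setting.

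ΔcIDR against KO compares both mutants with each other. ERVL and L1 intervals were lower in ΔcIDR relative to all intervals, at −1.10 ± 0.17 and −0.40 ± 0.18 (SE) on the log2 scale. The L1 value was −0.56 without ΔcIDR replicate 1 and −0.23 without ΔcIDR replicate 2. ERVK intervals lay 0.11 ± 0.02 (SE) above all intervals. Several intervals that fell in KO stood far higher in ΔcIDR. The ERVK interval on chromosome 9 (13668927 to 13669139) had 474.0 ± 70.6 against 6.40 ± 0.181 (SD, n = 2 each; 68.4-fold, limma adjusted p = 2.7e-77), and the ERV1 interval on chromosome 17 (6844428 to 6846145) had 540.7 ± 43.7 against 13.1 ± 3.16. An ERVK interval on chromosome 3 (6864661 to 6865008) had 253.2 ± 42.3 against 9.95 ± 2.72, and an ERV1 interval on chromosome 15 (22702358 to 22702615) had 34.2 ± 0.258 against 0.870 ± 0.111.

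In the other direction, the L1 interval on chromosome 3 (91049922 to 91050320) had 0.985 ± 0.0293 in ΔcIDR against 31.5 ± 5.79 in KO. An ERVK interval on chromosome 6 (19423070 to 19423420) had 1.56 ± 0.0696 against 25.7 ± 11.8, and an ERVL interval on chromosome 10 (108278359 to 108278559) had 1.39 ± 0.539 against 16 ± 2.53.

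The median interval lay 0.79 higher in ΔcIDR than in KO on the deposited scale. limma called 17846 higher and 592 lower, and edgeR called 18074. After centring there were 6654 higher and 3745 lower, so the share of higher calls went from 96.8% to 64.0%. With TMM factors edgeR called 5242 higher and 4642 lower. The share was 33.5% on the ERCC scale and 74.0% on the scale of reads in repeats outside intervals. The 18438 limma calls became 8409 without ΔcIDR replicate 1 and 11117 without ΔcIDR replicate 2. camera called ERVL (adjusted p = 1.2e-41) and L1 (adjusted p = 4.1e-12) below other intervals, and both reached adjusted p = 0.967 with an estimated correlation. After centring 22 ERVL intervals were higher and 983 lower, with 1182 passing adjusted over the list alone. For L1 the centred counts were 243 and 746, with 473 adjusted over the list alone. Of 58 families, 8 were higher and 0 lower on the deposited scale with limma, and 31 had an unadjusted p under 0.05. This count of 8 became 0 without either ΔcIDR or either WT library, 54 without KO replicate 1 and 38 without KO replicate 2. Its direction followed the scale, with 8 higher and 20 lower after centring and 1 higher and 47 lower on the ERCC scale. Satellite/Y-chromosome at 1.23 ± 0.32 and srpRNA at 1.19 ± 0.30 (SE; limma adjusted p = 0.00262 each) were among the largest changes. A single locus held 63.1% and 45% of their reads, and only 12.9% of Satellite/Y-chromosome loci lie on chromosome Y. ARTEFACT, which headed the list, had 93.9% of its reads on 1 locus.

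Signal also differed along chromosomes. Repeat loci outside intervals were used, after centring each library. Relative to WT, chromosome 6 stood at 0.35 (11425 loci) and chromosome 8 at 0.32 (11636 loci) on the log2 scale in KO, and at −0.16 and −0.19 in ΔcIDR. Both KO libraries showed it, at 0.36 and 0.34 on chromosome 6 and 0.31 and 0.33 on chromosome 8. On chromosome 11, the stretch from 8 to 56 Mb, whose bounds were picked from these values, stood at 0.51 in KO (4277 loci) and at −0.03 in ΔcIDR. Of the 28 bins of 10 Mb on chromosomes 6 and 8, 28 lay above 0 in KO and 27 below 0 in ΔcIDR. The 211 bins of the autosomes other than 6, 8 and 11 had a median of −0.057 (SD 0.11) in KO. These stretches held 4536 of the 37759 tested intervals but 22.8% of those called higher in KO on the deposited scale, and 29.7% after centring. The values from repeat loci had no test. As sets of intervals, after centring, camera placed chromosome 6 (adjusted p = 2.2e-07), chromosome 8 (adjusted p = 3.0e-05) and the stretch of chromosome 11 (adjusted p = 2.2e-13) above other intervals in KO, with adjusted p = 0.147, 0.494 and 0.147 with an estimated correlation. In ΔcIDR against WT it placed chromosomes 6 and 8 below other intervals (adjusted p = 0.00275 and 2.6e-04), and both had adjusted p = 0.534 with an estimated correlation.

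**Figure D3:**
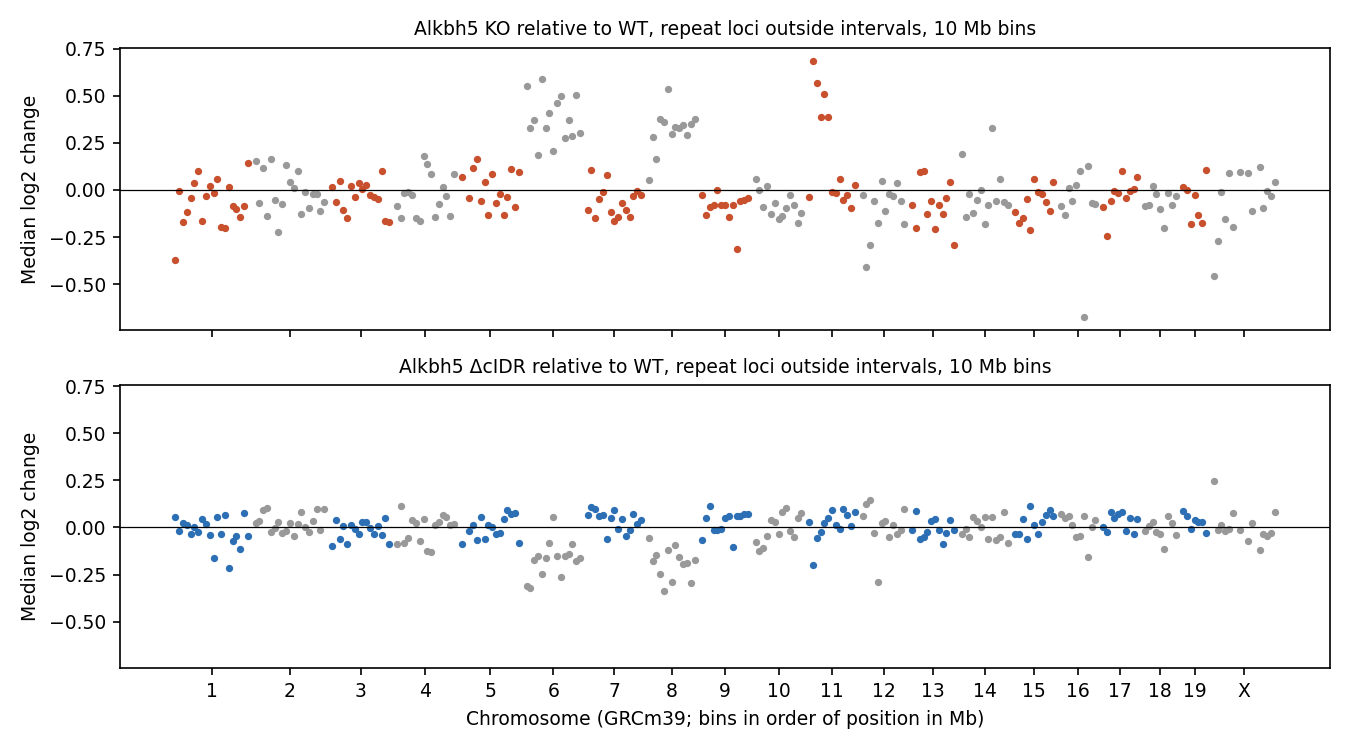
Median log2 change of repeat loci outside intervals in bins of 10 Mb, KO minus WT (top) and ΔcIDR minus WT (bottom), each library centred; each point is 1 bin and colours alternate by chromosome. In KO the bins of chromosomes 6 and 8 have a median of 0.34 and those of the autosomes other than 6, 8 and 11 have −0.057, and in ΔcIDR the bins of chromosomes 6 and 8 have a median of −0.17.

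Changes in the mutants, each relative to WT, were compared across 37759 intervals, which are not independent replicates. Their correlation was −0.077, where unchanged groups simulated against the same WT libraries gave 0.50. The covariance was −0.0198 against 0.0569 in the simulation, a difference of −0.0767. With 2 WT libraries the controls could not be split into separate pairs, and with 1 WT library left out the correlation was 0.16 without replicate 1 and 0.070 without replicate 2, where simulated unchanged groups gave 0.66 and 0.67. Calls higher in both mutants numbered 4 (3.87 for independent lists) and calls lower in both 5 (3.31 for independent lists), while 178 intervals were called in opposite directions (39.7 for independent lists). The deposited scale moves KO down and ΔcIDR up, and after centring 61 were called in opposite directions (7.02 for independent lists). Part of any excess of calls in the same direction may come from the shared WT libraries.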

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

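The tests of explanations given in this part, and the ERCC and repeat scales they use, were chosen only after the results had been seen. A screen of 35 repeat lists and chromosomes found 14 in which both KO libraries lay beyond both WT libraries on one side and both ΔcIDR libraries lay beyond both WT libraries on the other, each library centred. The screen used no p-value, and the differences at repeat loci were not tested. The largest were chromosome 6, at 0.35 in KO and −0.15 in ΔcIDR, chromosome 8, at 0.32 and −0.19, and chromosome Y, at 0.27 and −0.76 over only 67 repeat loci. Chromosome Y joined the screen after its values had been seen. Among intervals, ERV1 stood at −0.13 in KO and 0.062 in ΔcIDR, and intervals without a repeat at −0.081 and 0.17. These are means of medians per library. By the median of changes between group means, ERV1 stood at −0.10 in KO and −0.022 in ΔcIDR (0.031 without ΔcIDR replicate 2), so its opposite direction depends on the measure, while intervals without a repeat stood at −0.048 and 0.11. The remaining chromosomes moved little. KO and ΔcIDR stood at −0.030 and 0.044 on chromosome 2, −0.071 and 0.044 on 7, −0.078 and 0.044 on 9, −0.095 and 0.024 on 10, −0.10 and 0.021 on 12, −0.052 and 0.030 on 15, −0.068 and 0.035 on 16, −0.035 and 0.031 on 17, and −0.068 and 0.038 on 19. Part of these small values follows from centring, since a rise of some chromosomes lowers the others. As sets of intervals in ΔcIDR against KO, after centring, camera called chromosome 6 (adjusted p = 7.1e-09), chromosome 8 (adjusted p = 3.0e-08) and chromosome Y (adjusted p = 5.8e-08) lower and intervals without a repeat (adjusted p = 1.2e-10) higher. They had adjusted p = 0.189, 0.272, 0.346 and 0.692 with an estimated correlation. It did not call ERV1 (adjusted p = 0.366) or the other chromosomes named here.

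Signal also appeared in RNAs outside the comparisons. The ERCC RNAs had at least 90392 reads in each library, and the unmodified spike-in had at least 1729 reads. They are listed because reads were present in data outside the comparisons, which says nothing about the antibody.

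The first pattern is the higher total signal of ΔcIDR on the deposited scale. A technical candidate is a lower recovery of the m6A spike-in relative to other RNA in those libraries. The ERCC RNAs, which are not from the cells, stood 0.69 above WT on the same scale (SD 0.15 over 36 species), next to 0.61 for the intervals, and this is consistent with a shift carried by the spike-in. Whether more m6A in cellular RNA adds to it stays open. Scaled by ERCC reads, the total stood −0.049 ± 0.07 (SE) from WT, so no rise was left after that shift. Interval reads per read in repeats outside intervals were still 0.23 ± 0.02 (SE) above WT. The step at which the ERCC RNAs were added is not stated and input was not analysed here. That difference can therefore not be told apart from a change in which RNAs were present.

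The second pattern is the higher signal of KO on chromosomes 6 and 8. The rise was spread along both chromosomes, as 28 of 28 bins of 10 Mb lay above 0. Each bin is a median over at least 50 loci, which a few abundant loci could hardly move, so this count is no separate test of them. Extra copies of these chromosomes in KO relative to WT cells are a candidate explanation. The bins had a median of 0.34 (SD 0.12), below the 0.58 that 1 extra copy in all KO cells beside 2 copies in WT would give. Bins of the autosomes other than 6, 8 and 11 had −0.057. Intervals gave 0.33 and 0.26 where repeat loci gave 0.35 and 0.32. In ΔcIDR minus KO the bins of chromosomes 6 and 8 had a median of −0.52 (SD 0.18), and those of the other autosomes 0.053 (SD 0.14). Copy number was not measured here in any group, so WT may not be a 2-copy baseline. On chromosome 11 the stretch from 8 to 56 Mb stood at 0.51 in KO and the rest of that chromosome at −0.027. The bounds of that stretch were picked from these values. Loss of Alkbh5 itself stays open, since the 2 KO libraries that show the pattern share it. It cannot be told apart from a property of the cells used. As sets of intervals, the KO rise and the lower ΔcIDR values both passed camera only with the preset correlation. At repeat loci the ΔcIDR libraries stood at −0.16 and −0.14 on chromosome 6 and at −0.18 and −0.20 on chromosome 8, relative to the WT mean.

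The third pattern is the higher ERVL signal of KO. A rise held by a few intervals is argued against, as 93.3% of ERVL intervals lay above the median change of all intervals. How reads that match several copies were placed is not stated. A few source copies whose reads were spread over similar intervals therefore stay open. The shift of chromosomes 6, 8 and part of 11 is argued against, since ERVL intervals elsewhere stood at 0.93. With 0 columns read as input in the tables, more m6A per ERVL transcript cannot be told apart from more ERVL RNA. Loss of Alkbh5 and a difference between the cell populations, such as the share of cells that express these elements, both stay open and may act through either route.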

How the results depend on the processing

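Settings chosen after seeing the data were the ERCC scale, the scale of reads in repeats outside intervals, centring on total repeat signal, any overlap with a repeat, the block after centring, edgeR on the deposited scale and leaving out chromosomes 6 and 8 and 8 to 56 Mb of chromosome 11. Counts below are given as KO against WT, ΔcIDR against WT and ΔcIDR against KO, where the deposited scale gave 4156, 426 and 18438 intervals. Where no reason is stated, the cause was not tested.

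Without a filter on low values 2000 intervals were called in KO against WT and 43 in ΔcIDR against WT. A pseudocount of 2 gave 692 in ΔcIDR against WT. Centring gave 115 in ΔcIDR against WT and 10399 in ΔcIDR against KO, TMM factors 73 and 9884, the ERCC scale 54 and 9213, the scale of reads in repeats outside intervals 233 and 11407, and centring without the chromosomes above 102 and 8579. The unmodified spike-in scale gave 18, 1 and 97. Leaving out 1 library gave 667 to 10775, 30 to 10234 and 8409 to 20671. An arm left with 1 library is then assumed to vary like the others, and the KO libraries differ in scale, which adds to the pooled spread.

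Families numbered 0, 0 and 8 with limma on the deposited scale (2, 5 and 31 at an unadjusted p under 0.05), and all 8 were higher. They numbered 11, 12 and 28 after centring (7 higher and 4 lower, 4 and 8, 8 and 20), 27, 45 and 48 on the ERCC scale (25 and 2, 0 and 45, 1 and 47), 3, 2 and 22 on the scale of reads in repeats outside intervals, and 9, 6 and 21 after centring without the chromosomes above. Centring on total repeat signal gave 2, 0 and 24. In ΔcIDR against KO limma without trend gave 36, leaving out those chromosomes 31 and the unmodified spike-in scale 0. Leaving out 1 library gave 0 to 54, 0 to 47 and 0 to 54.

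Replicate numbers did not pair the libraries. Deviations from group means correlated at 0.076 between WT and KO, −0.29 between WT and ΔcIDR and −0.15 between KO and ΔcIDR. With the replicate number as a block, 2370 intervals were called in KO against WT, 90 in ΔcIDR against WT and 3 families in ΔcIDR against KO. The block after centring gave 77 and 8441 intervals in the ΔcIDR comparisons, against WT and KO, and 6, 8 and 24 families. Centring alone had given 115 and 10399 intervals and 11, 12 and 28 families, so most of that move came with centring. Against the deposited scale, neither form of the block moved another count by over 1.5 times.

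Of the repeat lists, camera called 6, 6 and 2 on the deposited scale, and 0, 0 and 0 with an estimated correlation, deposited or centred. Any overlap with a repeat, after centring, left 3 in ΔcIDR against WT. Simple and low complexity intervals relative to all intervals dcIDR vs WT went from −0.24 to 0.089 with any overlap, which takes in other intervals. The family DNA/Kolobok relative change dcIDR vs KO went from −0.14 to 0.0081 without the chromosomes above. Near 0, medians of ERV1, SINE B1, SINE B4/ID and satellite intervals in the ΔcIDR comparisons changed sign in some settings. With a pseudocount of 2, ERVL intervals relative to all intervals KO vs WT stood at 0.67.

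Total signal in ΔcIDR against WT went from 0.61 to −0.57 on the unmodified spike-in scale, −0.049 on the ERCC scale and 0.23 on the scale of reads in repeats outside intervals. Against KO it went from 1.02 to −0.38, −0.040 and 0.35, and KO against WT to −0.0082 on the ERCC scale. The correlation between mutant effects, −0.077, was 0.16 without WT replicate 1 and 0.070 without WT replicate 2. Unchanged groups simulated against 1 WT library gave 0.66 and 0.67, against 0.50 with both, and the covariance stood −0.062 and −0.092 from its simulated value.

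For the 60 interval results named by rule, 1153 of 1237 values under alternatives kept direction and call, 84 lost the call and 0 reversed. The unmodified spike-in scale lost 24 and the ERCC scale 10. Of 612 family values, 404 kept their call and 207 lost it. Of 420 values for repeat lists 341 moved by less than the replicate spread, and of 81 chromosome medians 57 did, 24 moved and 0 reversed. Not run, because the tables used hold 0 columns read as input, were the pairing of immunoprecipitated and input libraries and all input-level and WT enrichment results.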

Other observations

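The length classes described here, and the choice of ERVL, ERVK, ERV1 and L1 for them, were examined only after the interval results had been seen. The difference in ERVL signal between KO and WT was largest in long copies. Over 611 ERVL loci of at least 5 kb inside intervals, KO had 7082 ± 551 RPM and WT 3805 ± 419 RPM (SD, n = 2 each) of all repeat reads, a log2 change of 0.90 ± 0.14 (SE), 1.86-fold. Shorter ERVL loci inside intervals stood at 0.30 ± 0.07 (SE) over 1456 loci, and those outside intervals at 0.07 ± 0.02 (SE) over 91678 loci. In ΔcIDR relative to WT the long copies stood at −0.11 ± 0.15 (SE).

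L1 copies of at least 5 kb inside intervals did not separate the groups, at 0.10 ± 0.25 (SE) in KO and −0.24 ± 0.31 (SE) in ΔcIDR, both relative to WT. Shorter L1 copies inside intervals stood at −0.084 ± 0.12 (SE) in KO and −0.087 ± 0.13 (SE) in ΔcIDR. Those outside intervals, over 812659 loci, stood at 0.014 ± 0.019 (SE) in KO and −0.14 ± 0.0082 (SE) in ΔcIDR. These are ratios of summed reads without a test.

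Unmodified reads per m6A spike-in read were 3.91 and 1.56 in WT, 3.16 and 1.43 in KO and 6.30 and 4.99 in ΔcIDR, and the unmodified spike-in exceeded the m6A spike-in in all 6 libraries. ERCC reads ranged from 0.675% to 0.751% of interval reads. Simple repeats took 16.3% and 17.1% of repeat reads in WT, 15.5% and 15.6% in KO and 18.6% and 17.8% in ΔcIDR.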
